A study of Homo sapiens with 6 samples.

How the data were processed

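Gene expression was measured by RNA sequencing in 6 libraries of human breast cancer cells labelled MCF-7. Per the labels, 3 libraries came from cells cultured in air and 3 from cells cultured at 2% oxygen for 24 h. Groups and replicate numbers were taken from the sample labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

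The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the library's total of fragments), with 1 column per library and 62710 gene identifiers. Per the submitters' processing notes, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 were used with the human build hg38. The role of each tool, the gene annotation, read trimming, strand handling and the number of reads are not given in the sources used here. FPKM divides by each library's own total, so a few very abundant transcripts lower the values of all other genes in that library. The 6 columns summed to between 256754 and 318342 FPKM, which shows that they were not rescaled to a common total.

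Gene symbols were found for 42303 of the 62639 identifiers that matched the gene name table. Coordinates, gene types, transcript lengths and GC content were taken from GENCODE release 29 on the same assembly, GRCh38. Y-linked genes and XIST were left out, which left 62185 genes. RSEM assigns reads that fit several genes by estimation, so values of near-identical copies, such as the GAGE, XAGE, MAGEA and CSAG families, and of genes with many processed pseudogenes, such as ribosomal protein genes and FTH1, are uncertain. Overlapping and antisense genes are uncertain as well, since strand handling is not known.

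Values were transformed to log2(FPKM + 1). A gene was tested when it reached an FPKM of 1 in at least 3 libraries, which 12511 genes did. The comparison of the hypoxia with the normoxia libraries used limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance, without a replicate block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and no fold is given for a gene listed at 0 in all libraries of a group. With 3 against 3 libraries the smallest p of an exact permutation test is 0.1, so no such test could pass the threshold for a single gene.

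Before the data were examined, 34 gene lists were fixed, of which 26 were pathways or functions, 5 were cell type markers and 3 were signs of stress or RNA quality. Lists with at least 3 tested genes entered limma's camera test with a preset inter-gene correlation of 0.01, which asks whether a list moved relative to all other genes, with adjustment over 32 lists. The named genes were also fixed by rule. They were the 8 largest rises and the 8 largest falls among genes with a symbol, an adjusted p past the threshold, a mean FPKM of at least 5 and no overlap between groups. To these were added CA9, VEGFA, ADM, NDRG1, ANKRD37, EGLN3, BNIP3, PDK1, SLC2A1, PGK1, LDHA, HIF1A, EPAS1, ESR1, PGR and MKI67. Each pathway list gave the up to 3 members with the largest absolute change past the threshold, and each marker or quality list gave its most abundant member and its largest passing change. Any other gene named was chosen after its values were seen, mostly to spell out a small count.

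The low values of the libraries were used to estimate relative depth. For genes with a mean FPKM under 0.3, the commonest ratio of a library's value to that in normoxia library 1 gives the ratio of what 1 fragment is worth. Between 25.9% and 28.4% of the compared values lay within 0.005 of that ratio on the log2 scale. Relative to normoxia library 1, depth was 0.807 in normoxia library 2, 1.32 in normoxia library 3, and 1.01, 1.2 and 1.15 in hypoxia libraries 1, 2 and 3. Absolute depth is unknown, so no counting intervals are given.

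The test was tried on simulated data for this comparison, with 12511 genes of which 200 were changed and the spread of the real libraries. The 200 were drawn from genes with a mean log2(FPKM + 1) above 2, so recovery among genes of lower expression was not covered. It recovered 0% of changes of 0.5 on the log2 scale, 64% of changes of 1 with 6 false calls, and 94% of changes of 2 with 10 false calls. In the real comparison 69.4% of genes passed, which makes the adjusted threshold easier to reach than with 200 changed genes. These shares therefore do not give the recovery in the real data. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter and a filter at an FPKM of 5, rescaling to TPM, median-of-ratios scaling, trimmed-mean scaling, quantile normalization, limma without the trend and with a robust prior, the replicate number as a block, leaving out each library, a minimum change of 1, and for the lists an estimated correlation and fry. A correction for GC content, leaving out mitochondrial genes and small noncoding RNAs before rescaling, and leaving out normoxia libraries 1 and 2, which keeps 1 normoxia library, were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.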

Results

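The transcriptome of cells labelled MCF-7 was compared between culture in air and culture in low oxygen. MCF-7 is a human breast cancer line known for its luminal epithelial character and its estrogen receptor. The 3 libraries labelled normoxia and the 3 libraries labelled hypoxia (2% oxygen, 24 h) are called the normoxia and hypoxia libraries below, by their labels alone, because the marker genes described next did not match the labelled line. An FPKM of at least 1 was reached by 11235 to 11553 genes in the normoxia libraries and by 10920 to 11584 genes in the hypoxia libraries. FPKM values are means ± SD of the 3 libraries of a group unless stated otherwise.

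The receptors that define estrogen-receptor-positive breast cells, ESR1 and PGR, were close to 0 in all 6 libraries, while other luminal markers varied. ESR1, the estrogen receptor (chromosome 6, 151656691 to 152129619), had an FPKM of 0.00229 ± 0.00396 in the normoxia and 0.046 ± 0.00378 in the hypoxia libraries. PGR, the progesterone receptor, was listed at 0 in 5 of the 6 libraries. Of the 14 luminal markers, 2 reached an FPKM of 1 in every library, the keratins KRT8 and KRT18, and 6 stayed below 1 in every library, namely KRT19, ERBB3, SPDEF, AGR2, CDH1 (E-cadherin) and ESR1. Of the 8 luminal markers tested, 6 were higher in the hypoxia libraries, GATA3 was lower by 1.37 on the log2 scale, from an FPKM of 1.72 to 0.0514, and KRT18 did not pass (limma adjusted p = 0.33, log2 fold change 0.17). KRT18 passed as lower after quantile normalization (log2 fold change -0.31, adjusted p = 0.0369) and without mitochondrial genes and small noncoding RNAs (-0.30, adjusted p = 0.015). ELF3, an epithelial transcription factor, had 0.0131 ± 0.0123 in the normoxia and 15.7 ± 1.97 in the hypoxia libraries. The list did not pass camera (adjusted p = 0.0509), but did under 8 alternatives, among them TPM (0.0301), median-of-ratios scaling (0.0478) and leaving out hypoxia library 1 (0.0448).

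**Figure D1:**
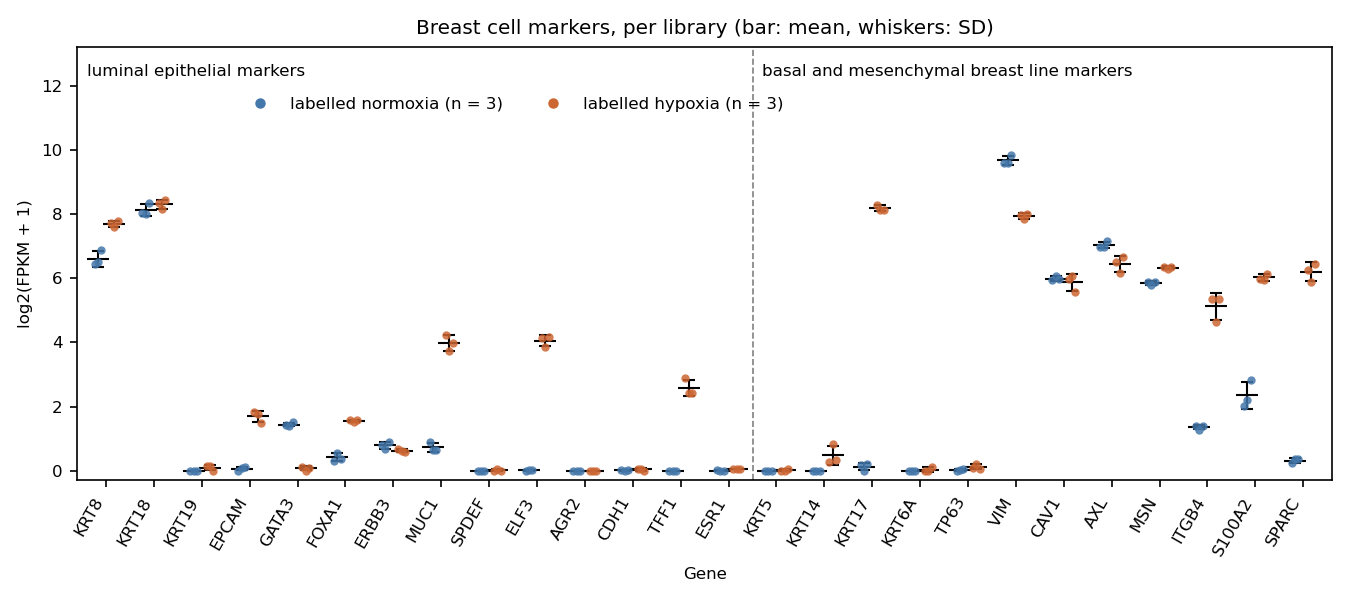
Expression of luminal markers and of basal and mesenchymal breast line markers in each library, as log2(FPKM + 1), with the mean and SD of 3 libraries per group. ESR1, CDH1, AGR2, SPDEF and KRT19 lie at or near 0 in all 6 libraries, and VIM is above 226 FPKM in all 6.

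Among markers of basal and mesenchymal breast lines, some were abundant in both groups and others nearly absent from the normoxia libraries. VIM, the mesenchymal intermediate filament vimentin, had an FPKM of 816 ± 85.7 in the normoxia and 244 ± 15.2 in the hypoxia libraries. KRT17, a basal keratin, had 0.0933 in the normoxia and 290 in the hypoxia libraries (log2 fold change 8.06, limma adjusted p = 2.27e-08). Of the 12 markers, 8 were tested, of which 5 were higher in the hypoxia libraries, VIM and the receptor kinase AXL were lower, and CAV1 had 62.5 and 58.2 (limma adjusted p = 0.494). The list did not pass camera (adjusted p = 0.191), but did without a filter (0.0322).

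The comparison of hypoxia with normoxia libraries asked which transcripts differ between the labelled groups. Low oxygen and any difference in cells between the groups would separate the same libraries, so neither this comparison nor the lists below can tell them apart. Of 12511 genes tested with limma, 8687 (69.4%) passed, 4766 higher and 3921 lower in the hypoxia libraries. Of all genes tested, 9138 (73%) had no overlap between the groups, against 10% by chance. The median log2 fold change over all genes was 0.07, with an interquartile range of -0.63 to 0.78, and 4351 genes passed with a change of at least 1. Pearson correlations of log values were 0.963 to 0.99 within groups and 0.662 to 0.738 between groups. When mitochondrial genes and small noncoding RNAs were left out before rescaling, 3345 genes were higher and 5765 lower (36.7% higher, against 54.9%), and the median of all genes moved to -0.32. With normoxia libraries 1 and 2, rich in small noncoding RNAs, both left out, 5085 genes passed. That setting keeps 1 normoxia library, so its spread comes from the hypoxia libraries alone and a call can be lost for lack of replicates. Of the genes named below IDH3G, TTK, KIF11, RBBP8, RAD51AP1, NOP58, RPL12, RPS2 and MALAT1 lost their call there and kept their direction (log2 fold changes 0.77, -1.72, -1.01, -1.21, -0.68, -1.66, 1.22, 0.98 and -1.07).

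The largest rises included secreted and surface proteins with almost no signal in the normoxia libraries. FOLR1, a folate receptor (chromosome 11, 72189558 to 72196323), had an FPKM of 0.364 ± 0.128 in the normoxia and 752 ± 54.9 in the hypoxia libraries (log2 fold change 9.11, SE 0.11, limma adjusted p = 2.27e-08). S100A6 and S100P, calcium-binding proteins, had log2 fold changes of 9.04 and 8.24. SLPI, a secreted protease inhibitor, had 8.57, KRT81, a hair keratin, had 8.26, and GPX1, a glutathione peroxidase that reduces peroxides, had 8.76, from 0.118 ± 0.0674 to 486 ± 68.6. CA9 and NDRG1, described with the oxygen-related genes, complete the 8 largest rises.

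The largest falls were mostly cancer-testis antigens of the X chromosome, genes normally silent outside the germline. GAGE2A (chromosome X, 49589529 to 49596827), GAGE2E and MAGEA4 had FPKM values of 495.5 ± 113, 164 ± 28.6 and 143 ± 22.1 in the normoxia libraries and were listed at 0 in all hypoxia libraries. GAGE12G, GAGE13, GAGE12J and XAGE1A had log2 fold changes of -8.70, -8.51, -7.54 and -7.38. UCHL1, a neuronal deubiquitinase (chromosome 4, 41256413 to 41268455), had 381 ± 53.7 in the normoxia and 0.511 ± 0.187 in the hypoxia libraries (log2 fold change -7.98, SE 0.14, limma adjusted p = 3.82e-08). In total, 87 genes were below an FPKM of 1 in all normoxia and at 20 or more in all hypoxia libraries, and 33 genes showed the reverse, 16 of them of the GAGE, XAGE, MAGE and CSAG families. MAGEB2, also of the MAGE family, went the other way, listed at 0 in the normoxia libraries and at 31.6 ± 1.21 in the hypoxia libraries. Members of these families share near-identical sequence, so the value of each single copy is uncertain.

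Genes of glucose uptake and glycolysis were higher in the hypoxia libraries almost without exception. Of 20 members, 19 were higher and PFKM did not pass (FPKM 19 and 17.8, limma adjusted p = 0.525). ALDOC, an aldolase, had 0.12 ± 0.0335 in the normoxia and 178 ± 9.3 in the hypoxia libraries (log2 fold change 7.32). HK2, the hexokinase that traps glucose, had 6.95 ± 0.686 and 250.1 ± 13.8, and ENO2, an enolase, had 9.23 ± 1.6 and 154 ± 12.9. SLC2A1, the glucose transporter GLUT1, had a log2 fold change of 3.86, PGK1 of 2.81 and LDHA, which makes lactate, of 3.02 (limma adjusted p = 7.49e-07, 4.77e-06 and 9.34e-07). The list passed camera (adjusted p = 8.6e-06, median log2 fold change 2.63), with adjusted p = 0.453 with an estimated correlation.

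Acid-handling and secreted factors followed the same direction for most members. CA9, a carbonic anhydrase at the cell surface that is induced by hypoxia-inducible factors (chromosome 9, 35673856 to 35681159), had an FPKM of 0.154 ± 0.0786 in the normoxia and 411 ± 64.5 in the hypoxia libraries (log2 fold change 8.47, SE 0.14, limma adjusted p = 3.16e-08). Of 8 genes of pH regulation, 6 were higher, among them the lactate exporter SLC16A3 (log2 fold change 3.18), and CA2 and SLC4A7 were lower by 3.13 and 1.09 on the log2 scale. That list did not pass camera (adjusted p = 0.0956), but did without mitochondrial genes and small noncoding RNAs (0.0228). Of 12 secreted angiogenic and vasoactive factors, 11 were higher and SERPINE1 did not pass (648 and 805, limma adjusted p = 0.0947). ANGPTL4, ADM (adrenomedullin, a vasodilator) and STC1 had log2 fold changes of 5.70, 4.89 and 4.57, and VEGFA, the main angiogenic growth factor, had 3.65 ± 0.163 and 35.1 ± 3.67 (log2 fold change 2.95). The secreted factors passed camera (adjusted p = 0.000192, and adjusted p = 0.45 with an estimated correlation).

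**Figure D2:**
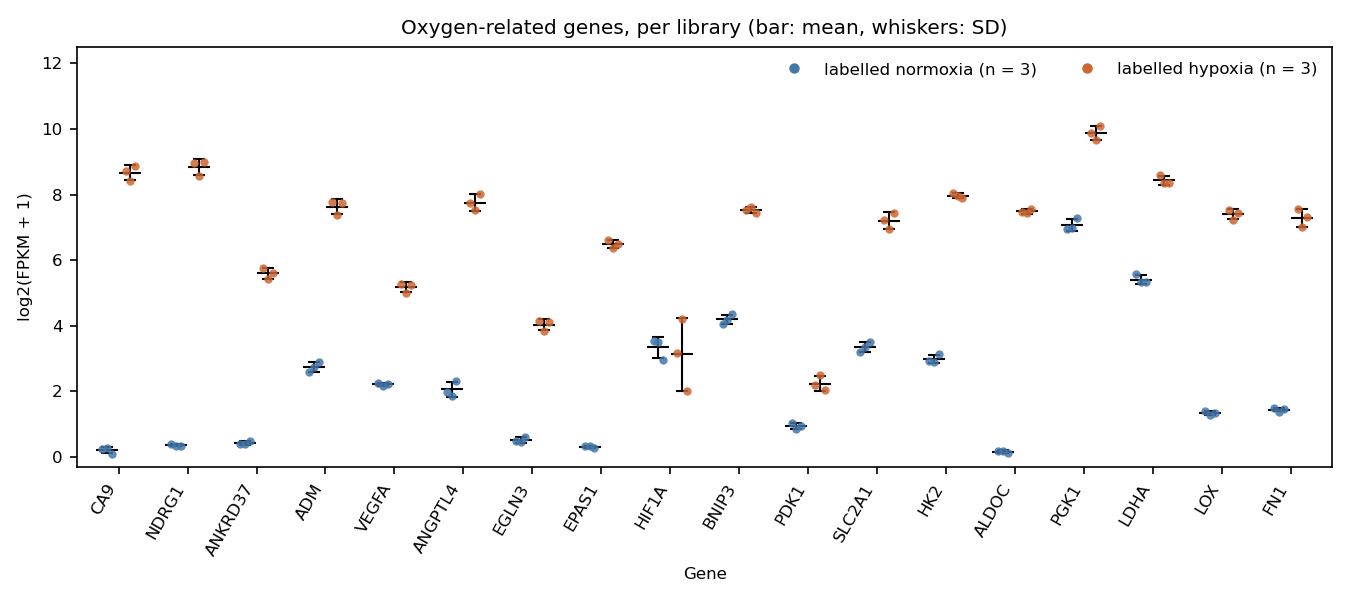
Expression of oxygen-related genes in each library, as log2(FPKM + 1), with the mean and SD of 3 libraries per group. All genes shown except HIF1A were higher in the 3 hypoxia libraries than in the 3 normoxia libraries, and HIF1A ranged from 3.01 to 17.6 FPKM among the hypoxia libraries.

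Oxygen sensing genes and HIF subunits differed unevenly. EPAS1, which encodes HIF-2α, had an FPKM of 0.236 ± 0.0363 in the normoxia and 89.2 ± 7.1 in the hypoxia libraries (log2 fold change 6.19, limma adjusted p = 3.46e-08), while HIF1A had 9.27 ± 2.15 and 9.53 ± 7.43 (log2 fold change -0.21, adjusted p = 0.728, and 0.35 without hypoxia library 3). ARNT2, another HIF partner, was listed at 0 in the normoxia libraries and had 19.7 ± 2.75 in the hypoxia libraries. EGLN3, a prolyl hydroxylase induced by HIF, had a log2 fold change of 3.51, and EGLN2 was lower by 0.73 on the log2 scale. Of 11 genes tested, 8 were higher, EGLN2 was lower, and HIF1A and HIF1AN did not pass (HIF1AN 8.33 and 10.1). NDRG1, a stress-response gene, and ANKRD37, both known HIF targets, had log2 fold changes of 8.48 and 5.18. The list passed camera (adjusted p = 0.0203, adjusted p = 0.45 with an estimated correlation), and did not with a filter at an FPKM of 5 (adjusted p = 0.0648).

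Of 11 genes of mitochondrial restraint and mitophagy, 8 were higher, PDK2 was lower by 1.13 on the log2 scale, and FUNDC1 and HIGD1A did not pass (log2 fold changes 0.36 and -0.09). BNIP3, a mitophagy receptor, had an FPKM of 17.4 ± 1.89 in the normoxia and 184 ± 11 in the hypoxia libraries. MXI1, LONP1 and PDK1, a kinase that inhibits pyruvate dehydrogenase, had log2 fold changes of 2.67, 2.24 and 1.29. The list passed camera (adjusted p = 0.0461, adjusted p = 0.45 with an estimated correlation), but not without normoxia library 3 (0.0559) or with a filter at an FPKM of 5 (0.24).

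All 14 tested genes of collagen modification and matrix were higher in the hypoxia libraries. COL5A1, a fibrillar collagen, had an FPKM of 0.0722 ± 0.0298 in the normoxia and 125 ± 37.2 in the hypoxia libraries. LOX, which crosslinks collagen, had 1.55 ± 0.114 and 168.5 ± 17.4, and FN1, fibronectin, had 1.72 ± 0.105 and 157 ± 29.2. The list passed camera (adjusted p = 1.49e-05, median log2 fold change 3.23), with adjusted p = 0.45 with an estimated correlation.

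All 13 respiratory chain genes encoded by the mitochondrial genome were lower in the hypoxia libraries. MT-ATP6 had an FPKM of 4834 ± 379 in the normoxia and 603 ± 72.9 in the hypoxia libraries, and MT-ND6 and MT-ATP8 had log2 fold changes of -2.87 and -2.65. MT-ATP6 and MT-ATP8 overlap, and MT-ND6 lies opposite other transcripts, so their reads may not be fully separable. The list passed camera (adjusted p = 1.57e-05, median log2 fold change -1.85), with adjusted p = 0.45 with an estimated correlation. Mitochondrial genes, their ribosomal RNAs included, made up 24.2%, 25.4% and 18.2% of the FPKM sum of normoxia libraries 1, 2 and 3. In hypoxia libraries 1, 2 and 3 they made up 6.46%, 8.04% and 6.1%. The protein-coding ones alone made up 18.3%, 16.1% and 15.6% in the normoxia libraries and 3.76%, 4.54% and 3.69% in the hypoxia libraries. Small noncoding RNAs made up 3.77% and 8.28% in normoxia libraries 1 and 2 and at most 0.28% in the other 4 libraries.

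**Figure D3:**
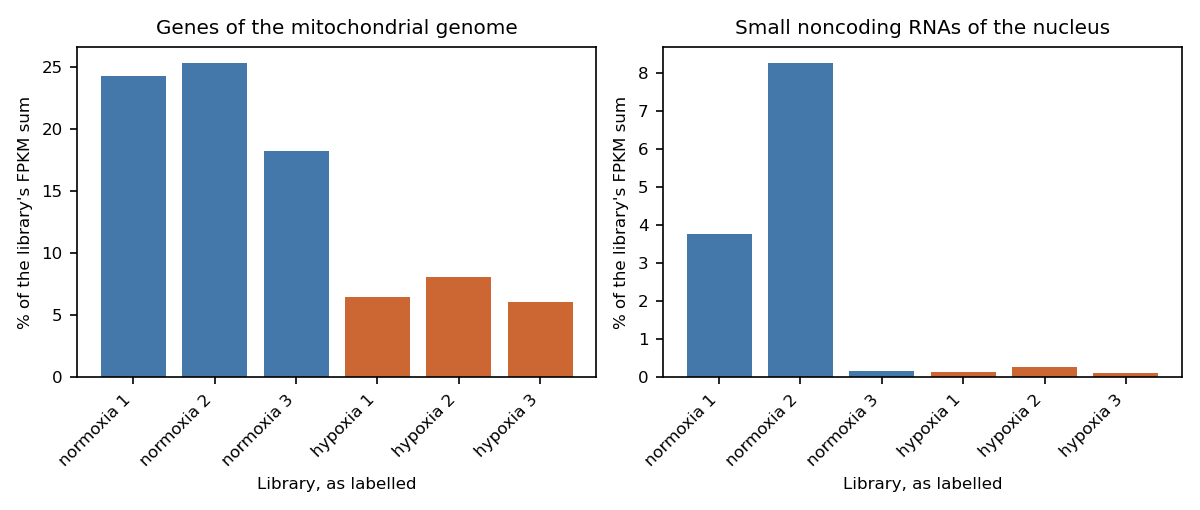
Share of each library's FPKM sum, in percent, taken by genes of the mitochondrial genome (left) and by small noncoding RNAs of the nucleus (right). The mitochondrial share lies between 18.2% and 25.4% in the normoxia and between 6.1% and 8.04% in the hypoxia libraries, and small noncoding RNAs stand out in normoxia libraries 1 and 2.

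The nuclear-encoded respiratory chain subunits did not follow the mitochondrial ones. Of 58 subunits, 25 were higher, 9 lower and 24 did not pass (camera adjusted p = 0.316, median log2 fold change 0.30). The direction depended on the scaling, with 18 higher and 22 lower when mitochondrial genes and small noncoding RNAs were left out, and 19 and 20 after quantile normalization. SDHA, a subunit of succinate dehydrogenase, and UQCRC1, of complex III, had log2 fold changes of 2.57 and 2.12, and COX6B1, of cytochrome c oxidase, had -1.61. Of 16 citric acid cycle genes, 8 were higher, CS, IDH3B and MDH2 were lower, and 5 did not pass (camera adjusted p = 0.353). IDH2, a mitochondrial isocitrate dehydrogenase, had 3.08 ± 1.01 in the normoxia and 59.5 ± 11.1 in the hypoxia libraries, and IDH3G had a log2 fold change of 0.91. Without mitochondrial genes and small noncoding RNAs, 4 citric acid cycle genes were higher and 4 lower, with a median of -0.13 against 0.31.

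Ribosome synthesis factors and MYC targets were lower in the hypoxia libraries. Of 24 genes, 19 were lower, PES1 and NOB1 were higher, and NOLC1, POLR1C and RRP9 did not pass (log2 fold changes -0.22, -0.30 and -0.34). RRS1, a ribosome assembly factor, had an FPKM of 43 ± 3.54 in the normoxia and 5.23 ± 1.16 in the hypoxia libraries, and NOP58 and NOP16 had log2 fold changes of -2.02 and -1.24. The list passed camera (adjusted p = 0.00039, median log2 fold change -0.79), with adjusted p = 0.453 with an estimated correlation. Of 36 cytosolic ribosomal proteins, 16 were higher, RPL7 and RPS16 were lower (log2 fold changes -1.54 and -0.92), and 18 did not pass, while 7 were higher and 8 lower without mitochondrial genes and small noncoding RNAs. That list did not pass camera (adjusted p = 0.0956), but did without a filter (0.0091), with the replicate block (0.0305), without normoxia library 3 (0.0356) and without hypoxia library 2 (0.0435). RPL12 and RPS2 had log2 fold changes of 1.43 and 1.24.

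Genes of the cell cycle moved in both directions. Of 35 DNA replication genes, 19 were higher, 7 lower and 9 did not pass (camera adjusted p = 0.426), against 7 higher and 14 lower without mitochondrial genes and small noncoding RNAs and 11 and 11 after quantile normalization. FEN1, a flap endonuclease, RFC5, a clamp loader subunit, and RRM1, of ribonucleotide reductase, had log2 fold changes of 1.74, 1.39 and 1.36. Of 24 mitosis genes, 5 were higher (AURKA, AURKB, KIF2C, BIRC5 and UBE2C), 7 lower and 12 did not pass (camera adjusted p = 0.505), against 2 higher and 13 lower without mitochondrial genes and small noncoding RNAs and 10 higher and 6 lower after GC correction. TTK, a spindle checkpoint kinase, had an FPKM of 8.98 ± 3.52 in the normoxia and 1.15 ± 1.08 in the hypoxia libraries, UBE2C had a log2 fold change of 1.21, and the proliferation marker MKI67 had 8.77 ± 2.75 and 5.87 ± 2.72 (log2 fold change -0.55, limma adjusted p = 0.184, and 0.00708 with the replicate block). KIF11, a spindle motor, had a log2 fold change of -1.42 (limma adjusted p = 0.034) with overlapping groups. Its call was lost without normoxia library 1 or 2 or hypoxia library 1 or 3 (-1.36, -1.28, -1.41 and -0.89), without a filter, and after GC correction (-0.82), with adjusted p between 0.00189 and 0.434 over its alternatives. Of 16 genes of homologous recombination and Fanconi repair, RAD51 was higher, RBBP8, XRCC3, RAD51C and RAD51AP1 were lower, and 11 did not pass (camera adjusted p = 0.426), against 0 higher and 8 lower without mitochondrial genes and small noncoding RNAs, 0 and 4 with TPM, and 3 and 3 after GC correction. RBBP8 and XRCC3 had log2 fold changes of -1.69 and -1.11, and RAD51AP1 had -0.76 (limma adjusted p = 0.048). The change of RAD51AP1 vanished after GC correction (-0.02), and its call was lost when normoxia library 1, 2 or 3 or hypoxia library 1 or 3 was left out (-0.82, -0.66, -0.80, -0.75 and -0.46), without a filter, with a pseudocount of 0.1 and without a limma trend, with adjusted p between 0.00252 and 0.922 over its alternatives.

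Stress response genes were mixed. Of 19 genes of the unfolded protein and integrated stress response, 10 were higher, ASNS, CHAC1, PSAT1, DNAJB9 and ERN1 were lower, and ATF4, HSP90B1, SDF2L1 and DNAJC3 did not pass (log2 fold changes -0.08, -0.43, -0.43 and 0.33; camera adjusted p = 0.505). ERO1A, an oxidase of the endoplasmic reticulum, and PPP1R15A had log2 fold changes of 2.80 and 2.28, and ASNS, asparagine synthetase, had -1.86. Of 18 p53 targets, 14 were higher, RRM2B and CCNG1 were lower, and MDM2 and ZMAT3 did not pass (log2 fold changes -0.54 and -0.33). CDKN1A, the cell cycle inhibitor p21, had an FPKM of 27.3 ± 3.17 in the normoxia and 226 ± 35.4 in the hypoxia libraries, and BTG2 and GDF15 had log2 fold changes of 4.49 and 4.38. The p53 list passed camera (adjusted p = 0.0203, adjusted p = 0.45 with an estimated correlation), but not with a filter at an FPKM of 5 (0.0535). Of 14 NRF2 antioxidant genes, GCLC, G6PD and PRDX1 were higher, SLC7A11, TXNRD1, SRXN1 and GCLM were lower, and 7 did not pass (camera adjusted p = 0.471), against 0 higher and 9 lower without mitochondrial genes and small noncoding RNAs, 0 and 4 with TPM, and 2 and 9 after quantile normalization. TXNRD1, a thioredoxin reductase, had 353 ± 20.1 and 78.5 ± 13.9, and SLC7A11, the cystine transporter, had a log2 fold change of -2.70. The median of the NRF2 list was 0.02, while its mean of -0.34 and its camera direction were negative, as was its median under every scaling alternative.

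Lipid genes also split. Of 18 genes of lipid droplets and fatty acid metabolism, 6 were higher, 10 lower, and FADS1 and SREBF1 did not pass (log2 fold changes 0.16 and -0.03; camera adjusted p = 0.265). The lipid droplet proteins HILPDA and PLIN2 had log2 fold changes of 4.65 and 4.17, and FABP5, a fatty acid carrier, had 84.4 ± 10.1 in the normoxia and 10.8 ± 0.443 in the hypoxia libraries. Of 21 cholesterol synthesis genes, 10 were lower, 5 were higher (NSDHL, EBP, DHCR24, INSIG1 and PCSK9) and 6 did not pass (camera adjusted p = 0.162). SQLE, which epoxidizes squalene, and EBP had log2 fold changes of -2.34 and 2.20, and PCSK9 was listed at 0 in the normoxia libraries. Of 11 iron and heme genes, 8 were higher, CYBRD1 was lower, and HMOX1 and IREB2 did not pass (log2 fold changes 0.21 and -0.56; camera adjusted p = 0.0956). FTH1, the ferritin heavy chain, had 148.5 ± 18.6 and 4355 ± 415, TFRC, the transferrin receptor, had a log2 fold change of 2.53, and CYBRD1 had -2.58.

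Immune and inflammatory genes moved in both directions within each list. The interferon response, NF-kappa-B and epithelial to mesenchymal transition lists did not pass camera. They passed as higher by limma's fry, which does not compare a list with other genes (fry adjusted p = 0.000334, 0.000125 and 2.14e-05). The epithelial to mesenchymal transition list holds both epithelial and mesenchymal genes, so its direction does not say whether the transition rose. Of 15 interferon response genes, 5 were higher (ISG15, IFI6, IFITM1, IRF7 and BST2), 6 lower, and IFIT1, IFI44, OAS3 and STAT2 did not pass (log2 fold changes -0.31, -0.21, 0.20 and 0.02; camera adjusted p = 0.755). BST2, the surface protein tetherin, had an FPKM of 0.167 ± 0.0429 in the normoxia and 169 ± 6.2 in the hypoxia libraries, and IFITM1 and ISG15 had log2 fold changes of 3.02 and 2.08. The median of this list was -0.21 and its mean 0.51. Of 14 NF-kappa-B inflammatory targets, 7 were higher, 6 lower and NFKBIA did not pass (13.7 and 14.1; camera adjusted p = 0.605). CXCL2, a chemokine, had 195 ± 35.8 and 1.14 ± 0.105, CXCL8, another chemokine, was listed at 0 in the normoxia libraries and had 37.5 ± 9.54 in the hypoxia libraries, and TNFAIP2 had a log2 fold change of 5.09. Of 13 genes of the epithelial to mesenchymal transition, 6 were higher, VIM, OCLN, CDH2, ZEB1 and MMP14 were lower, and TWIST1 and TGFB1 did not pass (log2 fold changes 0.22 and 0.16; camera adjusted p = 0.505), with a median of 0.22, of -0.17 without mitochondrial genes and small noncoding RNAs, and of -0.12 after GC correction. ITGA5, an integrin that binds fibronectin, MMP2 and the tight junction gene CLDN4 had log2 fold changes of 4.72, 3.95 and 3.83.

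Of 15 oxygen-dependent chromatin demethylases, 9 were higher, KDM5A and RIOX2 were lower, and KDM3B, KDM4A, KDM7A and TET3 did not pass (log2 fold changes 0.25, 0.22, 0.29 and 0.03). The demethylases did not pass camera (adjusted p = 0.0509), but did under 4 alternatives, among them no filter (0.0261) and leaving out normoxia library 1 (0.0404) or hypoxia library 3 (0.042). JMJD6, KDM6B and KDM5C had log2 fold changes of 2.18, 1.68 and 1.55. Of 13 tested estrogen receptor targets and coregulators, 9 were higher, GATA3, CCND1 and IRS1 were lower, and XBP1 did not pass (32.7 and 32.9; camera adjusted p = 0.0654, but 0.0398 with TPM, 0.0228 without mitochondrial genes and small noncoding RNAs and 0.0491 without hypoxia library 2), while the other 11 members of the list, ESR1 and PGR among them, did not reach the filter. IGFBP4, AREG and CTSD had log2 fold changes of 3.64, 3.06 and 2.74. Of 7 hypoxia-associated long noncoding RNAs, 6 were higher and MALAT1 was lower. H19, an imprinted transcript, had an FPKM of 0.169 ± 0.0312 in the normoxia and 128 ± 39.3 in the hypoxia libraries, UCA1 was listed at 0 in the normoxia libraries, and MALAT1 had 62.9, 48.3 and 5.78 in normoxia libraries 1, 2 and 3. This list passed camera (adjusted p = 0.0351, adjusted p = 0.45 with an estimated correlation), but not without normoxia library 3 (0.0617) or with a filter at an FPKM of 5 (0.0703).

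**Figure D4:**
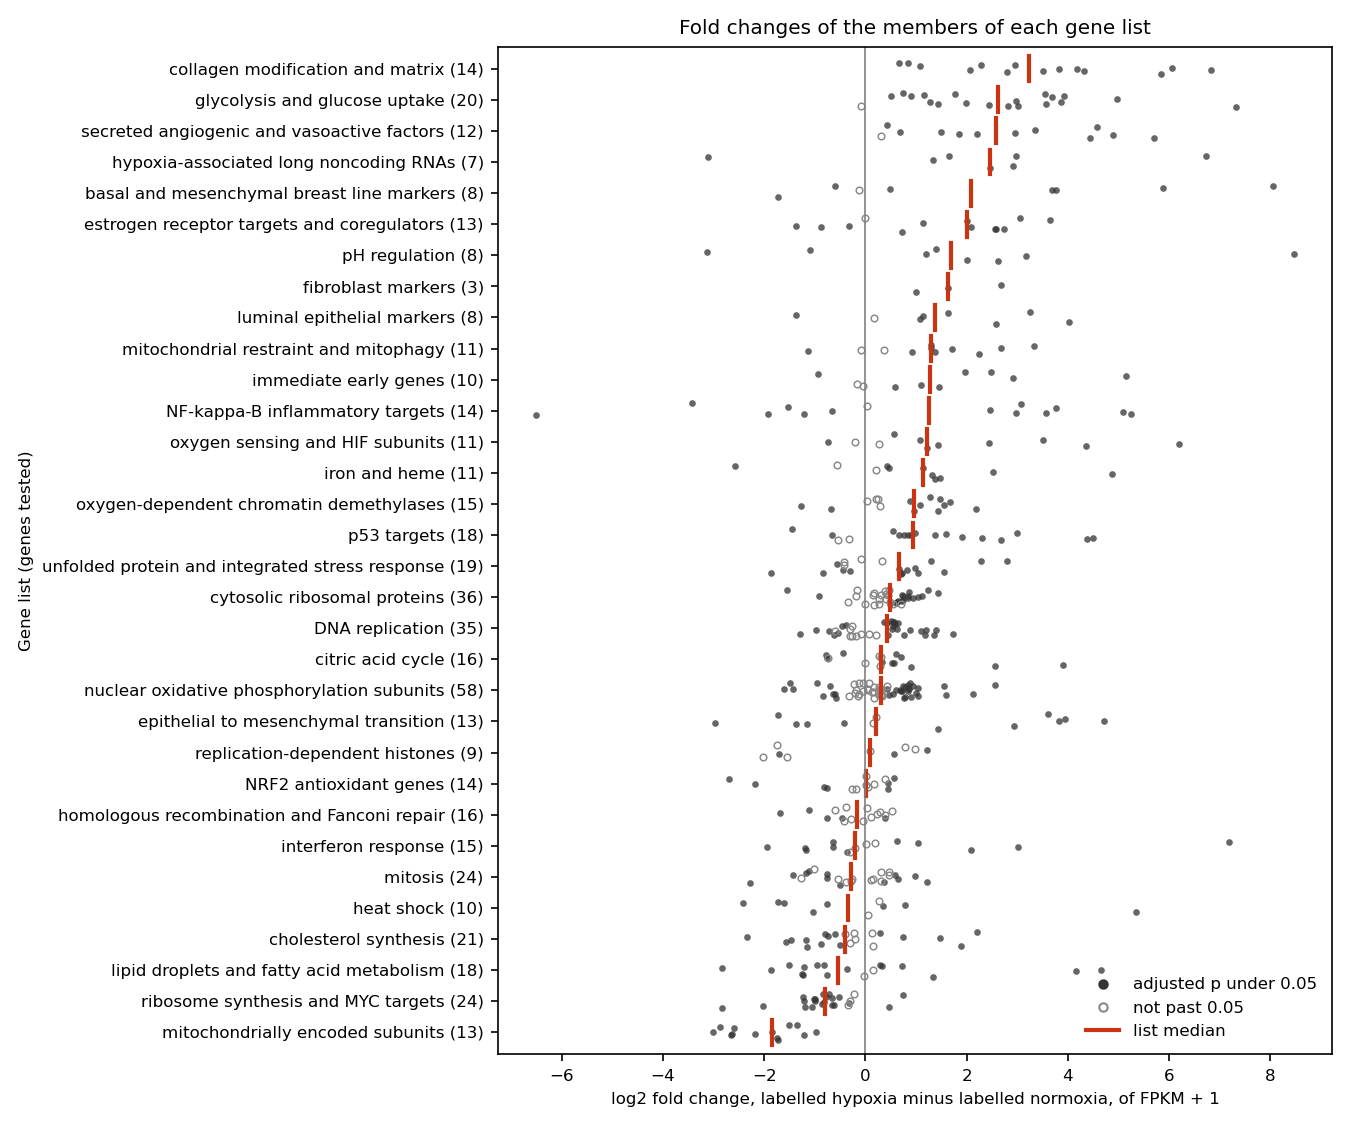
Log2 fold changes (hypoxia minus normoxia libraries, of FPKM + 1) of every tested member of the 32 lists with at least 3 tested genes, with filled points for an adjusted p under 0.05, open points for the rest and red bars for list medians. Medians run from -1.85 for mitochondrially encoded subunits to 3.23 for collagen modification and matrix.

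Markers of other cell types were mostly below the filter. Of 10 fibroblast markers, COL1A1, PDGFRB and FBN1 were tested and all were higher in the hypoxia libraries, with FBN1, a microfibril protein, at 2.53 and 21.8. The fibroblast list did not pass camera (adjusted p = 0.0509), but did under 13 alternatives, among them TPM (0.0301), quantile normalization (0.0426) and median-of-ratios scaling (0.0454). Of 10 leukocyte markers, CD68 and LCP1 were tested and were higher, with CD68 at 25.2 and 136, and PTPRC was listed at 0 in all 6 libraries. Of 8 endothelial markers, ESAM and ENG were tested and were higher, with ESAM at 0.757 and 19.7. Of 10 immediate early genes, 7 were higher, ZFP36 was lower, and EGR1 and IER2 did not pass (log2 fold changes -0.05 and -0.17; camera adjusted p = 0.0834, but 0.0175 without a filter and 0.0419 without mitochondrial genes and small noncoding RNAs), with DUSP1 at 7.64 and 304. Of 10 heat shock genes, HSPB1, HSPA1A and DNAJB1 were higher, HSPA8, HSPH1, HSPE1, HSPD1 and HSP90AA1 were lower, and HSPA1B and BAG3 did not pass (log2 fold changes 0.26 and 0.05; camera adjusted p = 0.605), with HSPB1 at 2.53 and 140.1. Of 9 replication-dependent histones, H2AC6 and H4C14 were higher, H2BC12 was lower and 6 did not pass (camera adjusted p = 0.742), against 0 higher and 1 lower without mitochondrial genes and small noncoding RNAs, and 6 higher and 1 lower with normoxia libraries 1 and 2 left out, where 1 normoxia library remains. Their median was 0.10 and their mean -0.37, and some differed within the normoxia group along with the small noncoding RNAs, as did H3C2 at 10.4, 23.7 and 0.21 in normoxia libraries 1, 2 and 3.

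In all, 9 of the 32 lists passed camera, 7 higher and 2 lower in the hypoxia libraries, and 0 passed with an estimated correlation. By limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 24 lists passed. Adjusted over the list alone, the counts of higher and lower genes were as given, except for 9 higher in oxygen sensing, 7 lower in the interferon response, 0 higher and 3 lower in homologous recombination, and 1 higher among the histones. Across 10749 protein-coding genes, which are not independent replicates, the fold change between groups had a Spearman correlation of 0.37 with GC content. Contrasts within groups had correlations of larger size, -0.53 for normoxia libraries 1 and 2 against 3 and -0.73 for hypoxia library 2 against 1 and 3.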

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

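GC correction, leaving out mitochondrial genes and small noncoding RNAs, and leaving out normoxia libraries 1 and 2 were chosen after the data were seen. The count of 8687 changed genes lay between 7603 and 9089 when each library was left out in turn, fell to 5007 with a filter at an FPKM of 5, since fewer genes were tested, to 5085 with normoxia libraries 1 and 2 both left out, which keeps 1 normoxia library and no spread within that group, with 5046 genes shared, and to 4351 with a minimum change of 1. It was 11989 of 32418 genes without a filter. The 9 lists past the camera threshold became 15 without a filter, 5 with a filter at an FPKM of 5, 24 by fry and 0 with an estimated correlation, and 8 to 12 when each library was left out. The scaling moved the median log2 fold change of all genes from 0.07 to -0.05 for TPM, -0.07 for quantile normalization and -0.32 without mitochondrial genes and small noncoding RNAs; relative to that median, nuclear respiratory chain subunits lay at 0.23, 0.23, 0.00 and 0.16, and cytosolic ribosomal proteins at 0.42, 0.42, 0.21 and 0.35. HIF1A had 0.52 with GC correction and 0.17 without normoxia libraries 1 and 2, and ranged from -0.75 to 0.35 when each library was left out. KRT18 had -0.31 with quantile normalization (adjusted p = 0.0369), -0.15 with GC correction, -0.30 without mitochondrial genes and small noncoding RNAs (adjusted p = 0.015) and -0.05 without normoxia libraries 1 and 2. Camera's direction turned for the interferon response without a filter (median 0.02), at an FPKM filter of 5 (2.08) and without normoxia libraries 1 and 2 (-0.10). Fry's direction for that list differed from camera's at the main setting (-0.21, fry adjusted p = 0.000334). For nuclear respiratory chain subunits camera's direction turned with quantile normalization (-0.06), and for heat shock fry's direction differed from camera's (-0.35). For histones camera's direction turned without mitochondrial genes and small noncoding RNAs (-0.18), without normoxia libraries 1 and 2 (0.84) and without normoxia library 2 alone (0.62). The histone median ranged from -0.41 to 0.62 when each library was left out. The cause was not tested for these. Of the values recomputed for the named genes, 2182 kept their direction and side of the threshold, 24 lost the call, 1 gained it (MKI67 with the replicate block, adjusted p = 0.00708) and 7 turned. Most named genes were chosen for large changes, so these numbers do not hold for all genes. Of the 8687 calls, 7467 were also made with GC correction and 7229 without mitochondrial genes and small noncoding RNAs. Of the list values 628 kept their direction and side of the threshold, 15 lost the call, 50 gained it and 9 turned. Labels share replicate numbers, and the values do not settle whether the numbers pair the libraries. Deviations from the group mean correlated at 0.011, 0.374 and 0.434 between same-numbered libraries. Between libraries of different numbers they correlated at 0.374, -0.391, -0.208, -0.276, 0.143 and -0.495. Normoxia libraries 2 and 3 correlated best with their own number, and normoxia library 1 with hypoxia library 2 (0.374). With the replicate block 9296 genes and 10 lists passed. Depth is known only as a ratio between libraries, so it is not known how far low values are limited by counting.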

Other observations

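The tests on CDKN2A and respiratory chain subunits, on low oxygen, on small noncoding RNAs and on S phase were set after the values had been seen, and those on 10 Mb windows, GC correction and splits of the libraries before. Outside the fixed lists, genes below an FPKM of 1 in each normoxia library and at 20 or more in each hypoxia library included CXCR4, a chemokine receptor, IGFBP7, TGFBI, TIMP3, an inhibitor of matrix proteases, L1CAM, MCAM, TXNIP and the transcription factors TFAP2C and TBX3. The reverse was seen for HOXB2, HOXB4, MDK, a secreted growth factor, ANKRD1, STEAP1 and the germline gene TDRD12. These genes were picked from the table after their values were seen.

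A total of 120 genes were off (below an FPKM of 1) in all libraries of a group and high (at least 20) in all libraries of the other. Of the 116 with a GC value, 100% stayed past the threshold after GC correction. Genes picked for so large a change would mostly stay past it in any case, so that share decides nothing about a GC content bias. Their median absolute log2 change was 5.34 after correction against 5.41 before, so a smooth trend with GC content accounts for little of its size. If the groups came from different cells, copy number could move neighbouring genes together. Among 4253 genes expressed in both groups, 10 Mb windows held 22.33% of the variance in GC- and length-corrected fold change. The most in 1000 shuffles of gene positions was 7%. Contrasts within the normoxia and hypoxia groups held 8.3% and 10.34%. These also exceeded all of their own shuffles, so exceeding the shuffles is by itself no sign of different cells. A larger share between groups is what different cells would give. Contrasts within a group hold no treatment difference, so the share cannot tell different cells from low oxygen acting on neighbouring genes. Other reasons for neighbouring genes to move together were not tested. The window at 30 to 40 Mb of chromosome 19 had a median of -1.46 over 38 genes and that at 0 to 10 Mb of chromosome 5 had 1.28 over 11. Low oxygen acting on 1 cell population stays open, since it separates the same libraries. Of the 120 genes, 7 belong to the hypoxia-related lists or were named in advance, above the 0.82 expected by chance and far from most of them. The lists hold few genes and not every oxygen target, so they could hardly make up most of the 120. This count therefore does not argue against low oxygen.

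Of the 14 luminal markers, 6 stayed below an FPKM of 1 in all 6 libraries, ESR1 among them, although the label names a luminal line. A failure of whole libraries is argued against, since 58 of 58 nuclear respiratory chain subunits reached an FPKM of 1 in every library. UQCRC1 and COX6B1 among them had at least 26.95 and 67.81 in every library. Subunits this abundant cannot tell whether depth or estimates failed for single genes such as ESR1. For the labelled line after a loss of luminal expression, genes of a deletion were examined, since MCF-7 is known to lack CDKN2A and its neighbour MTAP. The test was first set for MTAP and left the question undecided. MTAP lay between 2.28 and 5, above the value of 1 that the deletion allows but not at the 5 set before it was seen. CDKN2A was taken in its place after its values were seen, so it is no independent test. Its lowest value was 11.46 FPKM, which argues against the labelled line with that limit. Other causes were not tested.

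Small noncoding RNAs that lack a poly(A) tail were high in normoxia libraries 1 and 2. RN7SK had 1170, 2794 and 3.58 FPKM in normoxia libraries 1, 2 and 3 and 3.26, 26.6 and 4.73 in hypoxia libraries 1, 2 and 3, and 35 of 67 small RNA genes were higher in both normoxia libraries than in each other library. More cells in S phase is argued against, since DNA replication genes differed by a median of -0.12 on the log2 scale between those libraries and normoxia library 3 (quartiles -0.18 and -0.03). A library preparation that kept RNA without a poly(A) tail may account for it, as replication-dependent histones, which also lack the tail, lay 1.32 higher (9 genes). The labels name no difference in preparation, and no biological explanation other than S phase was tested.

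Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave 8687 changed genes and the highest of the others gave 0. So few splits cannot give a share under 0.05.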
